A study of Mus musculus with 6 samples.

How the data were processed

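The samples were mouse embryonic stem cells that had been differentiated toward sinoatrial node-like cardiomyocytes, the pacemaker lineage of the heart. Per the labels' protocols, the stem cell clones were kept on mouse embryonic fibroblasts, differentiated in hanging drops and sorted by flow cytometry for the surface protein CD166, which Alcam encodes, at stage 7+1 days. RNA was extracted with TRIzol, and 500 ng of total RNA per sample went into RNA sequencing on an Illumina HiSeq 2000. The labels name 3 samples wild type and 3 samples Shox2 knockout. The 3 titles labelled knockout share 1 clone-like prefix and the 3 titles labelled wild type carry 3 different ones, so genotype and stem cell clone cannot be told apart. How the knockout allele was made, the library kit and its strandedness are not given in the sources used here. No label says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical in part. The titles also carry Diff numbers, 9, 9 and 811 for the samples labelled wild type and 7, 8 and 9 for those labelled knockout, whose meaning is not stated.

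The deposited files list an Ensembl gene ID, a symbol and 1 value for each of 30631 genes in each library. Per the submitters' processing notes, CASAVA 1.8.2, BWA, HTSeq, DESeq2 1.14.0 and genome build mm10 were used, with no role or order stated for the tools. The unit was worked out from the values: the deposited numbers are gene-level read counts divided by 1 size factor per library, which brought the library totals to between 22414189 and 23844338. Low values were whole multiples of 1 step per library, and division by that step gave whole reads for 100% of values within a tolerance of 0.1 reads. Median-of-ratios size factors computed anew from the recovered reads matched the recovered steps. The recovered reads came to 13504683, 34650564 and 29916220 in libraries 1, 2 and 3 labelled wild type. They came to 13782017, 26199927 and 31151471 in libraries 1, 2 and 3 labelled knockout. Library 1 of each group was the shallowest and therefore carried the larger counting error, so that a value of 10 there stood for fewer than 10 reads. Because the counting is not stated to use strand, overlapping and antisense genes share an uncertainty of assignment, which concerns Shox2 and its neighbour Rsrc1. Gene positions were taken from the GENCODE release M21 annotation of GRCm38, the assembly also called mm10, in which 30484 of the listed IDs were found. A gene-level value cannot be divided between exons, introns and untranslated regions.

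Values were analysed as log2(value + 1) in R 4.3.3 with limma 3.58.1 (linear model with 1 term for the labelled group, empirical Bayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment), after keeping genes with a value of at least 10 in at least 3 libraries, which left 17034. A fold change on this scale understates the change of low genes. A gene was called at an adjusted p under 0.05. The design fixed before the data were examined had assumed raw counts and named limma on log2(value + 1) as the fallback for other units. The fallback was used because the files hold normalized values. The planned edgeR test and its DESeq2 alternative were not run, and the recovered reads, which rest on an estimated step, served only alternatives and the comparison of library pairs. The 39 gene lists were also written before the data were examined, that of Shox2 targets named by the study as remembered. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at a correlation estimated from the data, and with fry, each adjusted over the 39 lists. Members were also adjusted over the list alone.

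Tested on simulated data, 10 simulations of 3 against 3 libraries with 17034 genes, 200 of them changed, recovered 59.5% of 2-fold and 94.3% of 4-fold changes, with 10.2 false calls per simulation and 0 calls in the wrong direction. A list of 30 genes shifted by 0.5 on the log2 scale was called by camera in 10 of 10 simulations, and 2 of 200 unshifted lists fell under 0.05. Changed genes and list members were drawn only from genes with a mean value of at least 50, so recovery among lower genes was not measured. The simulated genes varied independently of each other, and each had the same spread beyond counting in every library. In the data, the estimated inter-gene correlation was 0.28 in the extracellular matrix list and 0.46 in the interferon list. The simulations therefore do not show how camera at the preset correlation behaves for such lists, nor the recovery with libraries of unequal spread.

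The genes named in the text followed a rule fixed beforehand: Shox2 and Alcam; every gene the study named as a Shox2 target and of a list of Shox2-linked genes from the literature; up to 8 called genes per direction, of which there were 0; up to 4 members of each list with the lowest p; and the sex chromosome genes. Some genes that the rule names are not reported here. Other genes are said to have been chosen after their values were seen. Alternatives covered other scalings, filters and pseudocounts, a minimum effect size, limma voom on the recovered reads with and without sample quality weights, other variance models, leaving out each library, and the libraries whose titles carry Diff9. Pseudocounts, voom without weights, the variance models, trimmed-mean scaling, the sum of libraries 1 and 2 labelled wild type, the removal of 5 chromosomes, and a block for the Diff9 libraries were added after the data were seen. Beyond the filter on low values, no gene or library was left out of the main test.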

Results

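Gene expression was measured by RNA sequencing in CD166-sorted sinoatrial node-like cardiomyocytes grown from mouse embryonic stem cells, with 3 libraries labelled wild type and 3 labelled Shox2 knockout. The design asks which genes depend on Shox2, a homeodomain transcription factor that pacemaker development requires. Between 13504683 and 34650564 reads per library had been assigned to genes. Libraries 1 and 2 labelled wild type were closer to each other than any other pair, with 2.50% variation beyond counting error. In the other 14 pairs it was 8.26% to 21.2%. Library 3 labelled knockout, which shares the title number Diff9 with both, lay nearer to them (8.26% and 8.52%) than library 3 labelled wild type did (16.6% and 16.4%). Libraries 1 and 2 labelled wild type still differed by more than counting error, at 14.5% of genes where 5% would be expected, which separate preparations of the same RNA could also do. They were kept as separate samples because the labels list them so. Library 3 labelled wild type and library 1 labelled knockout lay at opposite ends of the first principal component, at -57.7 and 65.6. This component held 41.7% of the variance.

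Reads of the targeted gene were higher, not lower, in the libraries labelled knockout. How the allele was made is not given, so reads from a remaining part of the gene would not contradict the labels. Shox2 (ENSMUSG00000027833; mm10 chromosome 3, 66971727 to 66981771, minus strand) had 89.6, 83.4 and 31.4 normalized counts in the 3 libraries labelled wild type and 201, 548 and 373 in the 3 labelled knockout. The means were 68.2 ± 32.0 (SD, n = 3) and 374 ± 174 (SD, n = 3), a 5.51-fold higher level in the libraries labelled knockout (log2 change 2.46, SE 0.50, 95% interval 1.30 to 3.62). The reads behind these values numbered 40 to 128 in libraries labelled wild type and up to 613 in those labelled knockout. Shox2 missed the threshold over all genes in limma (adjusted p = 0.201). Among 22 pacemaker genes it rose when adjusted over the list alone (adjusted p = 0.0157), and it also did so without each library in turn (0.0134 to 0.0432). Its first 382 bases overlap Rsrc1, a splicing-related gene on the plus strand chosen after its values were seen, which had a log2 change of 0.47. Every direction given hereafter is therefore a direction between labels. Alcam, which encodes the sorted protein CD166 (chromosome 16, 52248996 to 52454074), was at 6319 ± 415 (SD, n = 3) in libraries labelled wild type and 4598 ± 622 (SD, n = 3) in those labelled knockout, a log2 change of -0.47 (SE 0.12) with an adjusted p of 0.242.

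All 5 genes that the study, as remembered, named as Shox2 targets were lower in all 3 libraries labelled knockout than in any labelled wild type. Nr2f2, an orphan nuclear receptor of atrial and venous identity (chromosome 7, 70351944 to 70366735), was at 1511 ± 70.8 (SD, n = 3) in libraries labelled wild type and 737 ± 78.4 (SD, n = 3) in those labelled knockout, a log2 change of -1.04 (SE 0.12; adjusted p = 0.0954). Fkbp10, a collagen chaperone of the endoplasmic reticulum (chromosome 11, 100415697 to 100424824), had a log2 change of -0.72 (SE 0.12). Mcf2l, a guanine nucleotide exchange factor (chromosome 8, 12873806 to 13020905), had one of -1.07 (SE 0.18). Igfbp5, a secreted binding protein of insulin-like growth factors (chromosome 1, 72857932 to 72874884), averaged 8553 ± 2118 (SD, n = 3) and 3591 ± 929 (SD, n = 3), a log2 change of -1.25 (SE 0.24). Cav1, the main coat protein of caveolae (chromosome 6, 17306335 to 17341452), averaged 612 ± 318 (SD, n = 3) and 154 ± 73.5 (SD, n = 3), a log2 change of -2.01 (SE 0.48).

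Adjusted over the list alone, 5 of these 5 genes fell in limma, and they did so without each library in turn as well. Over all genes tested 0 passed, with adjusted p between 0.0954 and 0.226. As remembered when the lists were written, the study named these genes and chose them partly on these samples, so the count is not independent evidence of the list's direction. As a list it was called lower by camera (adjusted p = 1.34e-07) and by fry (adjusted p = 0.0110), but not with an estimated correlation (adjusted p = 0.408). For the same reason these list tests are not independent evidence either.

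**Figure D1:**
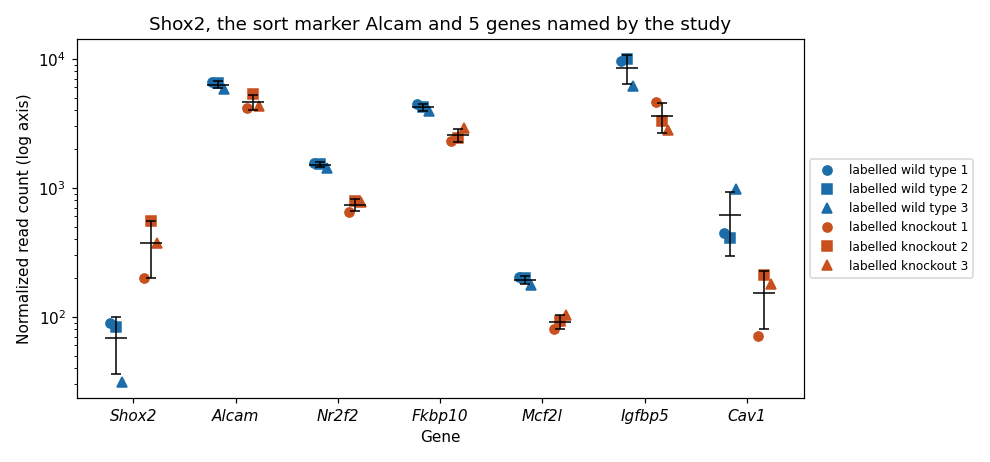
Normalized read counts (log axis) of Shox2, the sort marker Alcam and the 5 genes named by the study, with 1 point per library and black bars for the mean and SD of 3 libraries. Shox2 lies higher in the libraries labelled knockout (means 374 against 68.2), while the other 6 genes lie lower.

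Over the whole transcriptome, no gene passed the adjusted threshold. With limma on log2 values, 0 of 17034 genes were called (lowest adjusted p 0.0954), against 2411 at an unadjusted p under 0.05, where chance alone would give 851.7. Of these, 1179 were higher and 1232 lower in the libraries labelled knockout. The groups did not overlap in 23.6% of genes, where chance gives 10% for exchangeable libraries. Libraries 1 and 2 labelled wild type were too alike for that, so 10% is too low a mark if they are preparations of the same RNA. With these 2 libraries summed, 1583 genes had an unadjusted p under 0.05 in limma. Among the lowest adjusted p were those of Lpar6, a receptor for lysophosphatidic acid (log2 change 1.10), H19, an imprinted noncoding RNA (-2.85), the microfibril gene Mfap2 (-2.49), the villin-like gene Vill (-1.53), Nr2f2 (-1.04) and the integrin gene Itga1 (1.25). Lpar6, Mfap2, Vill and Itga1 were chosen after their values were seen. Limma voom called 303 genes with sample quality weights and 0 without. The main test called 51 without library 2 labelled knockout. Of the 303 calls 34, and of the 51 calls 18, lay on chromosome 14 from 73123037 on, where 111 of the tested genes lie, and 4 of each on the Y chromosome. That start was chosen from the values of the same libraries.

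Among pacemaker genes, members moved in both directions. Of 22 tested members of the sinoatrial list, 4 rose and 3 fell when adjusted over the list alone, with 0 passing over all genes. Besides Shox2, Isl1, a LIM homeodomain factor of cardiac progenitors and pacemaker cells, rose from 485 ± 22.9 (SD, n = 3) to 959.8 ± 379 (SD, n = 3). Bmp4, a secreted growth factor, rose from 1468 ± 67.3 (SD, n = 3) to 1844 ± 127 (SD, n = 3). Gjc1, which encodes a gap junction protein of pacemaker tissue and was chosen after its values were seen, rose by 0.63 (log2, SE 0.16). Igfbp5 fell, as did Pde1a, a cyclic nucleotide phosphodiesterase (log2 change -3.70, SE 0.90). Pde1a was at 131, 119 and 747 in libraries 1, 2 and 3 labelled wild type and at 5.19, 18.8 and 43.0 in those labelled knockout. Tbx18, a T-box factor of the sinus horns, fell from 162 ± 26.8 (SD, n = 3) to 72.5 ± 21.1 (SD, n = 3). The pacemaker channel gene Hcn4 averaged 223 ± 124 (SD, n = 3) and 275 ± 32.5 (SD, n = 3) and did not pass. Neither did Tbx3, a T-box repressor of the atrial program, at 381 ± 84.8 (SD, n = 3) and 715 ± 532 (SD, n = 3). The list as a whole was not called by camera (adjusted p = 0.434), and fry's test for change in either direction gave an adjusted p of 0.00225, a test that called 14 of the 39 lists. Shox2 and Igfbp5 passed without each library in turn. The counts of members that rose and fell became 1 and 2 without library 1 labelled wild type, 2 and 3 without library 2, and 3 and 7 without library 3. For the libraries labelled knockout they became 1 and 1 without library 1, 1 and 2 without library 2, and 3 and 3 without library 3.

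Genes tied to Shox2 in the literature, a list of 10 that includes Isl1, Bmp4, Tbx3 and Hcn4, had 6 higher and 4 lower members. In limma 0 of them passed, adjusted over the list alone or over all genes, and 3 had an unadjusted p under 0.05 (Isl1, Bmp4 and Nppa). Nppa, the atrial natriuretic peptide gene, had a log2 change of -1.10 (SE 0.44), and Gja5, which encodes an atrial connexin, one of -1.04 (SE 0.59). That of Tbx5, a T-box factor of the atria, was -0.38 (SE 0.44). Nkx2-5, a core cardiac homeobox gene that Shox2 is known to antagonise, was at 26.9 ± 8.93 (SD, n = 3) and 35.3 ± 25.3 (SD, n = 3). Gja1, the gene of the main ventricular connexin, had a log2 change of -0.01 (SE 0.30). Camera did not call this list (adjusted p = 0.411). Camera tests for a shift in 1 direction, and no expected signs were set for the members, so opposite changes would cancel. Fry's test for change in either direction did not call the list either (adjusted p = 0.313). Without library 3 labelled wild type 1 member passed, lower, and without library 3 labelled knockout 1 passed, higher. The signs of Hcn4, Nkx2-5 and Gja1 changed in some alternatives.

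No shift of the contractile program was called. The sarcomere list had 13 higher and 11 lower members of 24 (camera adjusted p = 0.735), the calcium handling list 7 and 10 of 17 (0.944), and the cardiac ion channel list 5 and 16 of 21 (0.152). Adjusted over the list alone in limma, 0 members of each passed. Camera called the sarcomere list higher with a block for the Diff9 libraries (adjusted p = 0.0256; 3 members rose over the list alone) and without library 1 labelled knockout (adjusted p = 0.0281), and the ion channel list without library 3 labelled wild type (0.0121) or library 3 labelled knockout (0.0402), or without the filter on low values (0.0467). Markers of atrial working myocardium were called lower by camera (13 of 16 members lower; adjusted p = 0.0286), although 0 members passed over the list alone and the adjusted p was 0.507 with an estimated correlation. Dkk3, a secreted Dickkopf family protein, had a log2 change of -0.95 (SE 0.26) and did not pass. This call was lost without library 1 (0.0908) or 2 (0.0555) labelled wild type, or library 1 labelled knockout (0.190), and with scaling by upper quartiles (0.0558) or a block for the libraries with Diff9 in their titles (0.0996). Of 33 cardiac transcription factors, Shox2 and Mef2c, a MADS-box factor of cardiac muscle (log2 change 0.80, SE 0.16), rose, and Nr2f2 and Tbx18 fell, adjusted over the list alone. Nr2f2 also passed without each library in turn. Mef2c was lost there without library 1 labelled wild type (adjusted p = 0.0729) or library 3 labelled knockout (0.0578), Shox2 without the latter (0.0578), and Tbx18 passed in 2 of the 6 left-out settings. In the ventricular list Mycn, a proliferation-linked factor, was the only member to pass over the list alone, and it rose (log2 change 0.98, SE 0.21; adjusted p = 0.0153). It was lost without library 2 (0.0523) or 3 (0.0531) labelled wild type.

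Extracellular matrix genes were lower as a group in the libraries labelled knockout. Of 49 members 45 were lower, with a median log2 change of -0.40, and camera called the list (adjusted p = 1.54e-08), but not with an estimated correlation (adjusted p = 0.479). Fry did not call it either (adjusted p = 0.245). Adjusted over the list alone, 3 fell in limma, and 0 over all genes. These were Fkbp10 and the genes of both type I collagen chains. Col1a1 fell from 24973 ± 6171 (SD, n = 3) to 10089.7 ± 2657 (SD, n = 3), and Col1a2 from 75019 ± 47059 (SD, n = 3) to 18258 ± 6043 (SD, n = 3). The Col1a2 value of library 3 labelled wild type was 129358, against 48014 and 47685 in libraries 1 and 2. Without library 1 labelled knockout 0 members passed, without library 3 labelled wild type 7 fell and 1 rose, and with a block for the Diff9 libraries 8 fell and 1 rose.

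Lists of mesenchyme, smooth muscle and epicardium, cell types that a CD166 gate could also hold, were called lower by camera. Of the mesenchyme list, the 10 members outside the matrix list had a median log2 change of 0.00082, with 5 higher and 5 lower. The mesenchyme list (12 of 17 lower; camera adjusted p = 0.00776, and 0.479 with an estimated correlation) had 4 members that fell adjusted over the list alone. They were Col1a1, Col1a2, the type III collagen gene Col3a1 (log2 change -0.98, SE 0.27) and Dpt, a matrix protein of connective tissue (-2.96, SE 0.75). Dpt was at 19.9, 15.6 and 109 in libraries 1, 2 and 3 labelled wild type and at 5.19, 1.79 and 3.70 in those labelled knockout. Of the 4 members only Col1a1 passed without each library in turn. The count was 1 without library 1 labelled knockout and 2 without library 2 or 3 labelled knockout. The smooth muscle list (8 of 11 lower; adjusted p = 0.00916, and 0.479 with an estimated correlation) had 3 members that fell over the list alone. Myh11, the smooth muscle myosin heavy chain, fell from 99.7 ± 32.0 (SD, n = 3) to 32.7 ± 9.45 (SD, n = 3). The others were Cnn1, calponin (log2 change -0.76, SE 0.19), and Des, desmin (-0.99, SE 0.25). Myh11 passed without each library in turn, alone without library 1 or 2 labelled wild type, and the list's own call was lost without library 1 labelled knockout (0.0758). In the epicardium list (9 of 11 lower; adjusted p = 0.00916, and 0.479 with an estimated correlation) Tbx18 fell. In the caveolae list (6 of 8 lower; adjusted p = 0.0351, and 0.507 with an estimated correlation) Cav1 fell. Tbx18 passed there in 2 and Cav1 in 3 of the 6 left-out settings. The epicardium call was lost without library 3 labelled wild type (0.200), and the caveolae call without that library (0.0791) or library 1 labelled knockout (0.134). With voom sample quality weights the smooth muscle (0.0593), epicardium (0.0673) and caveolae (0.0815) calls were lost, and with scaling by upper quartiles the caveolae call (0.0558).

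**Figure D2:**
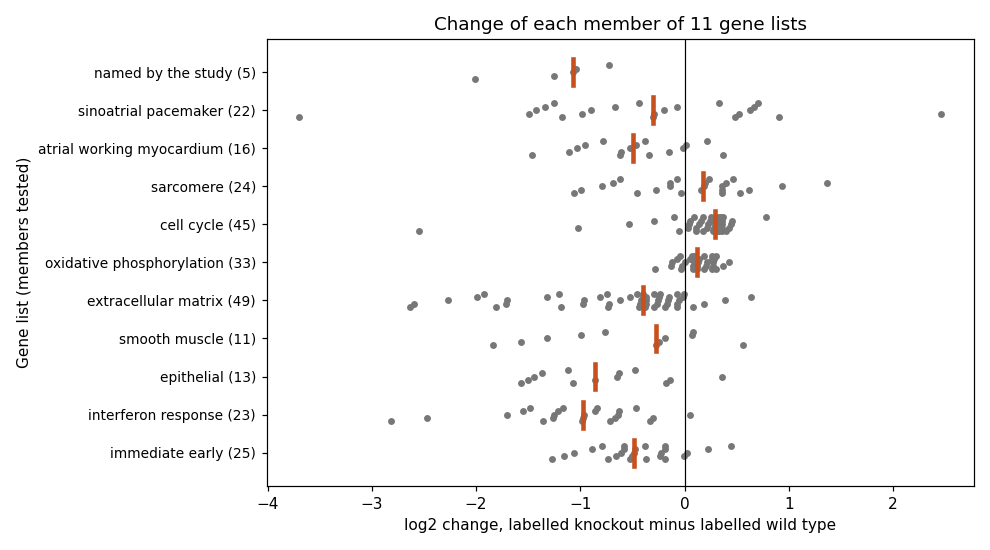
Log2 change between the libraries labelled knockout and those labelled wild type for each tested member of 11 gene lists (grey points, spread vertically for legibility), with the list median as an orange bar. The extracellular matrix median lies at -0.40 and the cell cycle median at 0.29, while the pacemaker members lie on both sides of 0.

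Epithelial and endodermal markers, signs of other cell types in the sort, were also lower. The epithelial list was not called by fry (adjusted p = 0.245). In it 12 of 13 members were lower (camera adjusted p = 2.50e-05, and 0.479 with an estimated correlation) and 7 fell adjusted over the list alone. Cdh1, E-cadherin, fell from 650.2 ± 28.1 (SD, n = 3) to 326 ± 137 (SD, n = 3), as did the tight junction gene Cldn7 (log2 change -1.37, SE 0.39) and the splicing factor gene Esrp1 (-1.44, SE 0.43). These calls were lost without library 1, 2 or 3 labelled wild type and without library 1 or 3 labelled knockout (0 each), and 9 passed without library 2 labelled knockout. Endodermal markers were lower in 18 of 22 cases (camera adjusted p = 0.000620, and 0.583 with an estimated correlation), with 0 passing over the list alone and 13 without library 2 labelled knockout. Afp, alpha-fetoprotein, was at 3313 ± 3210.4 (SD, n = 3) and 461 ± 345 (SD, n = 3). The neural list (12 of 16 lower) was called at an adjusted p of 0.0425, and 0.689 with an estimated correlation, with 0 members passing. The call was lost without library 3 labelled wild type (0.889), or library 2 (0.122) or 3 (0.132) labelled knockout. It was lost as well with scaling by library totals (0.0746) or upper quartiles (0.103), with the stricter filter (0.279) and with voom sample quality weights (0.778), while 6 members fell with a block for the Diff9 libraries. Among pluripotency markers, 5 higher and 12 lower of 17 (camera adjusted p = 0.245), 2 rose adjusted over the list alone and without each library in turn. Lin28a, an RNA-binding protein of stem cells, rose from 1516 ± 72.6 (SD, n = 3) to 3883 ± 1146 (SD, n = 3). Trim71, a stem cell RNA-binding ubiquitin ligase, rose from 2417 ± 238 (SD, n = 3) to 5759.9 ± 2201 (SD, n = 3).

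Interferon and immediate early genes were lower and cell cycle genes higher in the libraries labelled knockout. Fry called none of these lists (adjusted p = 0.245 each). Of 23 interferon response genes 22 were lower (camera adjusted p = 2.28e-07, and 0.479 with an estimated correlation). Oasl2, an antiviral oligoadenylate synthetase-like gene, fell adjusted over the list alone, from 246 ± 40.2 (SD, n = 3) to 105 ± 19.5 (SD, n = 3), and 18 members did without library 2 labelled knockout. Without library 1 labelled wild type or library 3 labelled knockout 0 did. Of 25 immediate early and stress genes, which respond to tissue dissociation, 22 were lower (4.39e-06, and 0.479 with an estimated correlation), and Ier2 (log2 change -0.59, SE 0.11) and Egr1 (-0.61, SE 0.14) fell over the list alone. In turn, 0 passed without library 1 or 2 labelled wild type or library 1 labelled knockout, and 8 without library 3 labelled knockout.

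In the cell cycle list 39 of 45 members were higher (camera adjusted p = 1.32e-06, and 0.479 with an estimated correlation). Over the list alone 3 rose, the mitotic checkpoint kinase gene Bub1 (log2 change 0.40, SE 0.09), the centromere histone gene Cenpa (0.45, SE 0.10) and the replication licensing gene Cdc6 (0.78, SE 0.18), while the inhibitor gene Cdkn2a fell from 175 ± 93.4 (SD, n = 3) to 28.4 ± 11.1 (SD, n = 3). This became 0 without library 1 or 2 labelled wild type or library 1 or 2 labelled knockout, while 9 rose and 1 fell without library 3 labelled wild type. With scaling by library totals or upper quartiles, or a block for the Diff9 libraries, 0 rose, and with voom sample quality weights 22 did. Oxidative phosphorylation genes were higher in 26 of 33 cases, with a median log2 change of 0.12 (adjusted p = 0.00241, and 0.479 with an estimated correlation) and 0 members passing. The histone and noncoding RNA list was called higher (11 of 13; adjusted p = 0.00916, and 0.599 with an estimated correlation), and the replication-dependent histone gene Hist1h3a rose over the list alone, as it did in 2 of the 6 left-out settings. That call was lost without library 3 labelled wild type (0.204) or library 3 labelled knockout (0.0838), and with voom sample quality weights (0.138).

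Signalling and metabolic lists held few members that passed. Of 37 Wnt genes Rspo3, a Wnt agonist, rose (log2 change 1.23, SE 0.21), and of 37 BMP and TGF-beta genes Bmp6 rose (1.20, SE 0.28) and Tgfb3 (-1.62, SE 0.34) and Tgfb2 (-0.54, SE 0.13) fell, adjusted over the list alone. Each of these 4 passed without only 1 of the 6 libraries, library 3 labelled knockout for Rspo3 and library 3 labelled wild type for the others, and 0 of the BMP and TGF-beta genes passed with a block for the Diff9 libraries. Nr2f2 fell among 17 retinoic acid genes, the death receptor gene Fas (-1.14, SE 0.20) among 19 p53 targets, and the acyl-CoA dehydrogenase gene Acadvl (-0.63, SE 0.13) and carnitine palmitoyltransferase gene Cpt1a (-1.39, SE 0.31) among 21 fatty acid oxidation genes. Fas was lost without library 2 labelled wild type (0.0657) and libraries 2 (0.0541) and 3 (0.0605) labelled knockout, and Acadvl and Cpt1a passed together only without library 3 labelled knockout. In the Notch, Hox, endothelial, haematopoietic, skeletal muscle, glycolysis, endoplasmic reticulum stress and mitochondrial genome lists, 0 members passed over the list alone in limma, and none of these lists or of those in this paragraph was called by camera (adjusted p from 0.0811 to 0.968). The endothelial (1.01e-05), haematopoietic (0.000326) and glycolysis (0.000739) lists were called without library 3 labelled wild type, and the haematopoietic list also without library 2 labelled knockout (0.0168). Without library 1 labelled wild type the stress (0.00879), mitochondrial (0.00297) and fatty acid oxidation (0.0304) lists were called, without library 2 the stress (0.00811) and mitochondrial (0.0343) lists, and without library 1 labelled knockout the mitochondrial list (0.0214). Voom sample quality weights called the endothelial (0.000806), haematopoietic (0.00439) and glycolysis (0.00260) lists, dropping the filter on low values the Wnt (0.0336) and skeletal muscle (0.00727) lists, the stricter filter the fatty acid oxidation list (0.0331), and a block for the Diff9 libraries the stress (0.00421) and mitochondrial (0.00930) lists. The embryonic globin gene Hbb-bh1, the leukocyte gene Ptprc and the connective tissue gene Ogn were chosen after their values were seen. Hbb-bh1 stood at 7441, 7150.4 and 60.5 in libraries labelled wild type and at 1524, 9696 and 1231 in those labelled knockout. Ptprc stood at 1151 in library 2 labelled knockout and at 525 or less in the other 5, and Ogn at 317, 291 and 10639 in libraries labelled wild type and at 69.2, 108 and 196 in those labelled knockout.

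Y-linked genes were lower in the libraries labelled knockout. Of 6 tested sex chromosome genes 5 fell adjusted over the list alone (camera adjusted p = 3.19e-05, and 0.479 with an estimated correlation): Zfy1, Kdm5d, Uty, Eif2s3y and Ddx3y, the Y-linked copies of genes for a zinc finger factor, members of the demethylase family, a translation factor and an RNA helicase. Kdm5d, Uty, Ddx3y and Eif2s3y stood at 10.6% to 22.2% of the wild-type mean in library 1 labelled knockout and at 18.6% to 27.4% in library 3, but at 53.9% to 95.7% in library 2. Without library 1 or 3 labelled knockout 2 of these genes passed. Xist, the RNA of the inactive X chromosome, was at 19.9, 29.3 and 5.50 in libraries labelled wild type and 1.73, 13.4 and 20.7 in those labelled knockout. By chromosome, over genes with a mean value of at least 50, the median log2 change of 717 genes of chromosome 8, where Mcf2l lies, was -0.19 relative to all genes, and 80.8% of them were lower. Genes of chromosome 1, which holds Igfbp5, Des and Col3a1, lay at a median of -0.29 in library 2 labelled knockout and between 0.01 and 0.12 in the others. On chromosome 14, 86.6% of 67 genes with starts between 73123037 and 115042879, Lpar6 among them, were above the wild-type mean in both library 1 and library 3 labelled knockout, a stretch chosen after its values were seen.

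**Figure D3:**
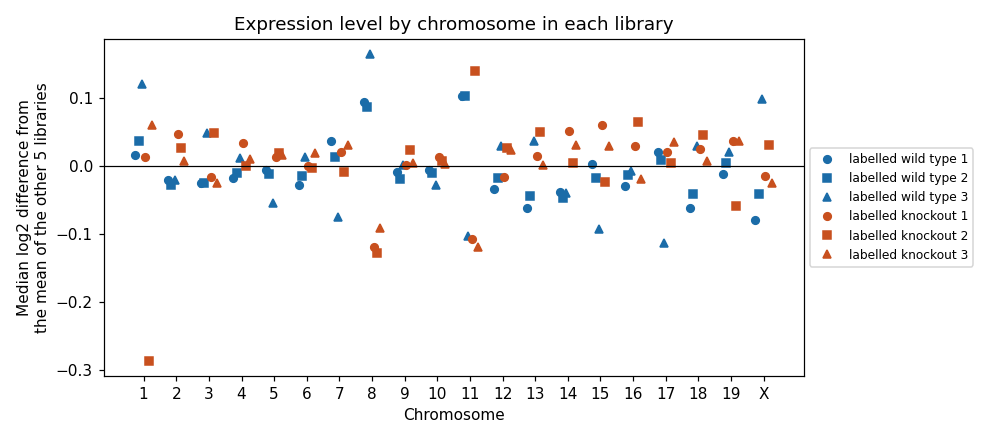
Median log2 difference of the genes of each chromosome (Y left out) between 1 library and the mean of the other 5, with 1 point per library. Library 2 labelled knockout lies at -0.29 on chromosome 1, and the 3 libraries labelled knockout lie below the 3 labelled wild type on chromosome 8.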

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

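The choices of pseudocount, voom without weights, variance model, trimmed-mean scaling, summed libraries, removed chromosomes and the Diff9 block were made after the data were seen, and the other alternatives before. The count of 0 called genes (2411 unadjusted) also held under other scalings, pseudocounts, the stricter filter, other variance models and voom without weights. Voom with sample quality weights called 303 genes, 170 higher and 133 lower (3809 unadjusted), giving library 3 labelled wild type a weight of 0.206 and libraries 1 and 2 weights of 3.59 and 4.22. There Shox2 stood at 2.15 (adjusted p = 0.0185), Hcn4 at -0.063, Gja1 at 0.19 and Hbb-bh1 at -1.45. Without the filter on low values 2 genes were called, 1 higher and 1 lower, and against a log2 fold change of 1 the unadjusted count was 89. Leaving out 1 library at a time gave 0 to 51 calls, 0 to 23 higher and 0 to 28 lower, above 0 only without library 2 labelled knockout, and 1487 to 2721 unadjusted. Shox2 then ranged from 1.98 to 2.85 (adjusted p 0.190 to 0.514), Hcn4 from -0.11 to 0.84, Gja1 from -0.26 to 0.28, Nkx2-5 from -0.32 to 0.48, Tnnt2 (chosen after its values were seen) from -0.49 to 0.067, Xist from -1.41 to 0.14, Hbb-bh1 from -1.47 to 1.99, Ptprc from -2.42 to 0.28, and the lists called by camera from 15 to 18. The libraries with Diff9 in their titles leave 1 labelled knockout, assumed to vary like the closely similar pair labelled wild type; they gave 3160 calls, 1562 higher and 1598 lower (5495 unadjusted), Shox2 2.10, Hcn4 -0.094, Hbb-bh1 -2.57 and Tnnt2 0.45. With a block for these Diff9 libraries against the other 3, 0 genes were called (2529 unadjusted), Shox2 stood at 2.73 and Tnnt2 at 0.082, and camera called 18 lists. With libraries 1 and 2 labelled wild type summed, 0 genes were called and 1583 passed unadjusted. Adjusted over the list alone in limma, that sum lost Isl1 (0.0982), Bmp4 (0.101), Mef2c (0.0652), Ier2 and Egr1 (0.0925 each), Bub1 (0.155), Cdkn2a (0.0588) and the epithelial members such as Cdh1 (0.0835), among others. Others kept passing, among them Shox2 (0.0369) and Igfbp5 (0.0401) in their lists, H19 (0.00193) and Nr2f2 (0.0119). Of 16 lists called by camera, 0 remained with an estimated correlation, while fry called 1 list, and 14 when change in either direction was tested. The 1 list called by fry was that of the genes named by the study, remembered as chosen partly on these samples. Of the named genes, 78 of which were tested, 7 changed sign under some alternative, in 18 of 1686 values. The called lists changed direction in 0 of 333 values and lost the call in 34. Except for the fewer libraries or genes and the weights themselves, the cause was not tested. The planned DESeq2 and edgeR fits were not run, since the fallback fixed beforehand for files without raw counts was used, the size factor alternative is already in the deposited values, and the alternative for differing gene IDs did not apply. No paired analysis was possible because the labels give no replicate numbers and the groups share only the Diff number 9, so that a block could only set apart the Diff9 libraries. Depth limits genes near the filter, where library 1 of each group had few reads.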

Other observations

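The lists of imprinted, insulin-like growth factor and extracellular matrix genes were fixed before the data were examined. Nodal and the genes given beside it, the tests by chromosome and the tests of explanations were chosen after the result was seen, except for leaving out each library, which was planned before.

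Imprinted genes, which are expressed from 1 parental allele, moved in both directions. Of 20 tested members 3 rose and 3 fell when adjusted over the list alone in limma, with 0 passing over all genes and no call by camera (adjusted p = 0.861). H19 (chromosome 7, 142575529 to 142578143), a noncoding RNA expressed from the maternal allele, fell from 83837 ± 18473 (SD, n = 3) to 12171 ± 5022 (SD, n = 3), a log2 change of -2.85 (SE 0.31). Its neighbour Igf2 (142650766 to 142666816), the paternally expressed growth factor gene, rose from 58835 ± 9931 (SD, n = 3) to 98609.9 ± 17701 (SD, n = 3). Igf2r, the receptor that clears this factor, rose by 0.50 (SE 0.14) and Mest, a paternally expressed hydrolase gene, by 0.89 (SE 0.18) on the log2 scale. Zim1 (log2 change -2.27, SE 0.56) and Plagl1, a zinc finger regulator of imprinted genes (-1.10, SE 0.27), fell. H19 and Mest passed without each library in turn. Plagl1 was lost without library 3 labelled knockout (adjusted p = 0.0664), and Zim1 and Igf2 without its library 1 (0.0705 each) or 3. Igf2 was also lost without library 1 labelled wild type (0.0537), and Igf2r passed only without library 3 labelled wild type or library 2 labelled knockout. In the list of insulin-like growth factor genes 3 members rose and 3 fell over the list alone, but only H19 and Igfbp5 passed without each library in turn.

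The genes in this paragraph were picked singly after their values were seen, were not tested as a list, and did not pass over all genes. Pluripotency markers as a list, fixed before, were not called by camera (5 higher and 12 lower of 17; adjusted p = 0.245). Nodal, a TGF-beta family morphogen, was at 107 ± 17.3 (SD, n = 3) in libraries labelled wild type and 281 ± 46.6 (SD, n = 3) in those labelled knockout (adjusted p = 0.133), and its nuclear cofactor gene Foxh1 had a log2 change of 1.36 (SE 0.23). Cfc1, a coreceptor of Nodal, had a log2 change of 2.31 (SE 0.37), while Lefty1, an antagonist of Nodal, had one of -1.53 (SE 0.49). Prtg, an early embryonic surface protein (1.45, SE 0.20), and Hmga2, a chromatin protein of embryonic cells (0.67, SE 0.16), also stood higher. The pericyte gene Rgs5 had a log2 change of 1.16 (SE 0.18).

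Shox2 stood 5.51-fold higher in the libraries labelled knockout, a log2 change of 2.46. Reads of the overlapping gene Rsrc1, counted for Shox2 at a constant share, are argued against by the log2 ratio of both genes, which differed by 1.99 (SE 0.70) between the labels. An exchange of 1 library labelled wild type with 1 labelled knockout is argued against as well, since 0 libraries labelled wild type lay above the lowest labelled knockout. That transcripts of the targeted locus were still made and counted, or that the labels of all 6 libraries were exchanged, cannot be told apart from gene-level values, because these give no exons. A response of the locus to the loss of its own product also stays open and was not tested.

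Stretches of chromosomes moved together in some of the libraries. In libraries 1 and 3 labelled knockout, 8 of 8 values of Kdm5d, Uty, Ddx3y and Eif2s3y lay below the lowest wild-type value. Library 2 labelled knockout met the same criterion in each gene. There Kdm5d stood at 602 (lowest wild-type value 893), Uty at 2451 (2709), Ddx3y at 4213 (4353) and Eif2s3y at 662 (817). Only the size of the drop therefore set libraries 1 and 3 apart. A Y chromosome missing from part of the cells of libraries 1 and 3 is a hypothesis drawn from these same values, so the count is no test of it. Cells with 2 X chromosomes are argued against by Xist, whose highest value in a library labelled knockout was 20.7, against 29.3 in a library labelled wild type. On chromosome 14, 86.6% of 67 genes whose starts lie between 73123037 and 115042879 were above the wild-type mean in both of these libraries (medians 0.80 and 0.86, and 0.34 in library 2), 24 of the 25 genes beyond were below it, and both ends were set from these data. An altered copy number is a hypothesis drawn from these same values. It was not tested, and the medians do not show what share of the cells would carry it. Without the genes of chromosomes 1, 8, 11, 14 and Y, 0 genes and 11 lists were called, and the caveolae (0.0545), mesenchyme (0.0551) and neural (0.206) calls were lost, while 2 lists kept too few members to be tested.

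Extracellular matrix genes were lower in the libraries labelled knockout, 45 of 49 of them. Library 3 labelled wild type, where collagens stood highest, is argued against as the whole source by the list median, which was -0.27 without it. Camera at the preset correlation still called the list then (adjusted p = 7.88e-06, the highest over left-out libraries, the lowest being 8.32e-11). That p adds little, because the wild-type group then held only libraries 1 and 2, which differed by just 2.50% beyond counting error. With all 6 libraries and an estimated correlation the list was not called (adjusted p = 0.479). The 10 mesenchyme members outside the matrix list had a median of 0.00082 with 5 higher and 5 lower, which by itself does not point to fewer mesenchymal cells in the sort. Their spread (scaled median absolute deviation 0.49) was wider than their distance from the matrix median of -0.40. Fewer mesenchymal cells therefore cannot be told apart from a lower matrix program. A dependence on Shox2 also stays open, since genotype and clone coincide.

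The real split of the 6 libraries gave 2411 genes at an unadjusted p under 0.05. The highest other split, the 3 Diff9 libraries against the rest, gave 1514, so that 1 of 10 splits gave a result as large. This share cannot decide the question, since 10 splits are too few for a share under 0.05. Nor are the splits alike. The other splits that kept the closely similar libraries 1 and 2 labelled wild type together gave 490, 1081 and 1514. Those that parted them gave 183 to 604. With a block for the Diff9 libraries, added after the data were seen, 2529 passed unadjusted and 0 were called. On chromosome 8, 7 of 7 bins of 20 Mb were lower in the libraries labelled knockout. On chromosome 1, 10 of 10 bins were lower in library 2 labelled knockout. Chromosome 11 lay at 0.10, 0.10 and -0.10 in the libraries labelled wild type and at -0.11, 0.14 and -0.12 in those labelled knockout.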
